A study of Danio rerio with 12 samples.

How the data were processed

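RNA was sequenced from whole zebrafish embryos carrying a knock-in at etv2, the gene of an ETS-family transcription factor that acts at the start of endothelial and blood development. The allele, etv2^Gt(2A-Gal4)ci32, places a 2A-Gal4 cassette at etv2, so that Gal4 switches on a UAS:GFP reporter in cells that express the gene. Per the labels, carriers were crossed with each other, and offspring were sorted as heterozygous or homozygous by their GFP pattern and frozen on dry ice. Embryos for the 15-somite stage were kept at 24 °C and those for 24 hpf (hours post fertilization) at 28 °C. Each library came from a batch of 15 to 20 embryos, with 3 libraries for each genotype at each stage and 12 in all. Per the labels' protocols, libraries were made with an NEBNext Ultra RNA kit.

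The authors deposited 1 table of normalized values per stage, with 31172 gene rows and 6 libraries each. The genome build Zv9 and the tool DESeq are named in the submitters' processing notes; the aligner, the read counter, the annotation release, strand handling and all versions are not given in the sources used here. The deposited values are on a log2 scale. From the values themselves, each had been floored at 1 before the log, and each row's median over the 6 libraries had then been subtracted. A deposited log2 value is therefore relative to the median of its own gene in its own stage, it holds no absolute level, and levels were never compared between genes or between the tables. In the table of the 15-somite stage, 2 columns carried the same homozygous name. Their genotype is known but not which batch each is, and they are called homozygous replicates a and b beside homozygous replicate 2. No column was left unused.

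Total depth is unknown, since the tables hold no counts. Steps between low values gave the worth of 1 read as 0.881 to 1.10 normalized units in the 15-somite libraries and 0.941 to 1.04 in the 24 hpf libraries. Relative depth thus spanned 0.902 to 1.13 and 0.961 to 1.06 within the stages. Only 43.8% to 56.3% of low values at the 15-somite stage and 45.8% to 54.5% at 24 hpf came out as whole reads within a tolerance of 0.001 read, so no count test was run. Numbers stored at finite binary precision keep a step set by their size, and this step survives subtraction. It gave the class of each row's median before subtraction: below 4, 4 to 16, 16 to 256, or 256 and above. Rows at 16 or above were tested, 18907 at the 15-somite stage and 19429 at 24 hpf, of which 62.8% and 62.3% lay at 256 or above. On simulated tables the class was right for 91.5% and 91.6% of rows, and 3.4% and 3.2% of the rows passed lay below 16. In the deposited tables, rows with several libraries at the floor have a known class, which was used for them. Of those known to lie below 16, the step alone placed 8.86% at the 15-somite stage and 15.34% at 24 hpf at 16 or above.

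Homozygous and heterozygous libraries were compared within each stage with limma 3.58.1 in R 4.3.3, without a replicate block. The moderated test's prior spread was estimated separately in the level classes, in place of a trend on mean level, which centred values do not hold. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all rows tested, two-sided. Every difference is homozygous minus heterozygous on the log2 scale, with its standard error (SE). The p-values of this test of single genes measure the spread between these libraries, each a batch of embryos. The difference of the genotype effect between stages was tested as a limma interaction over the 18139 rows tested at both stages. The overlap of calls between stages was tested with a one-sided Fisher's exact test. The share of calls on the chromosome of etv2 was tested with a two-sided Fisher's exact test, with chromosomes from the RefSeq annotation of assembly GRCz12tu. That assembly differs from the authors' build, so it was used only for names, chromosome membership and neighbourhood within 5 Mb. Current symbols were found for 20756 of the gene IDs.

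The following choices were made before the data were examined. They comprised 22 gene lists written from general knowledge of zebrafish development: endothelial, arterial, venous, blood progenitor regulators, myeloid, erythroid, skeletal muscle structure, myogenic and paraxial mesoderm regulators, cardiac, pronephros, neural, notochord, hatching gland, epidermis and ionocytes, endoderm, neural crest and pigment, lens, sclerotome with fibroblasts and mural cells, germ cells, hypoxia response, p53 response, and cell cycle. Lists with at least 3 tested members were compared with all other tested genes by camera in limma, with a preset correlation between genes of 0.01 and adjustment over the 22 lists of a stage. An estimated correlation and the fry test, which does not compare a list with other genes, were alternatives. The rule for named genes was also fixed: etv2 first, then per stage the 10 largest rises and 10 largest falls among called genes with separate groups, a high level and a descriptive symbol, then up to 4 members of each list with the smallest adjusted p, or 2 members where none passed. The planned mean levels of 10 for testing and 50 for naming were replaced by row medians of 16 and 256, because the tables hold no levels. Where no member of a list passed, the plan named the 2 with the highest mean. Instead the 2 were taken by highest level class and then by smallest p, so they are not typical members of their lists.

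Alternatives left out each library in turn, removed or moved the filter on level, normalized by quantiles, centred each library on its median, used 1 prior spread for all rows or a robust one, added a threshold of 2-fold, fitted all 12 libraries together, and added a replicate block where labels allowed it. Other pseudocounts, edgeR and DESeq2 were not used, because the values were already logged and were not counts. The test was run on simulated tables of the same design. Of genes changed 1.5-, 2- and 4-fold it recovered 22%, 57.3% and 85.7% at the 15-somite stage, with 5 false calls among 115 (4.3%), over 19040 simulated rows. At 24 hpf it recovered 44.6%, 73.8% and 86.6%, with 7 false calls among 142 (4.9%), over 19436 simulated rows. Noise was drawn independently for each gene, so variation shared by many genes of a library was absent. These shares therefore do not give the error rate in the real libraries. Symbols are printed as the tables give them. Hatching enzyme, keratin and globin genes have near-identical copies between which reads can be split, so values of single copies are uncertain, as are values of genes that overlap a gene on the other strand. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.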

Results

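Transcript levels were measured by RNA sequencing in whole zebrafish embryos that carried 1 or 2 copies of a Gal4 knock-in at etv2. The data comprised 12 libraries, 3 heterozygous and 3 homozygous at the 15-somite stage and 3 heterozygous and 3 homozygous at 24 hpf. Each library was made from a batch of 15 to 20 embryos. The tables hold normalized log2 values of 31172 genes relative to each gene's own median, so the total depth is unknown, and relative depth varied between 0.902 and 1.13 at the 15-somite stage and between 0.961 and 1.06 at 24 hpf. The first principal component separated the genotypes at both stages, with 40.8% of the variance at the 15-somite stage and 28.2% at 24 hpf, and no 2 libraries held identical values. Differences are homozygous minus heterozygous on the log2 scale, with n = 3 libraries per genotype. Libraries are called het 1 to het 3 and hom 1 to hom 3, and at the 15-somite stage the homozygous ones are hom 2, hom a and hom b.

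The targeted gene, etv2 (ENSDARG00000053868), was lower in every homozygous library. Relative to the geometric mean of the heterozygous libraries of its stage, it stood at 106%, 97.7% and 96.7% in het 1, het 2 and het 3 at the 15-somite stage, and at 16.3%, 13.3% and 12.9% in hom 2, hom a and hom b. At 24 hpf the heterozygous libraries stood at 101%, 99.2% and 99.6%, and hom 1, hom 2 and hom 3 at 13.8%, 7.40% and 14%. It fell by 2.83 on the log2 scale at the 15-somite stage (SE 0.10, 7.09-fold, adjusted p = 0.000785) and by 3.15 at 24 hpf (SE 0.24, 8.88-fold, adjusted p = 0.00646). Without het 1 or het 3 the 24 hpf difference was -3.14 and -3.15, with adjusted p = 0.0697 and 0.0527. The difference between the stages was -0.32 (SE 0.27, adjusted p = 0.577). The tables give 1 value per gene, so the part of the transcript that was read, relative to the insertion, was not determined.

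**Figure D1:**
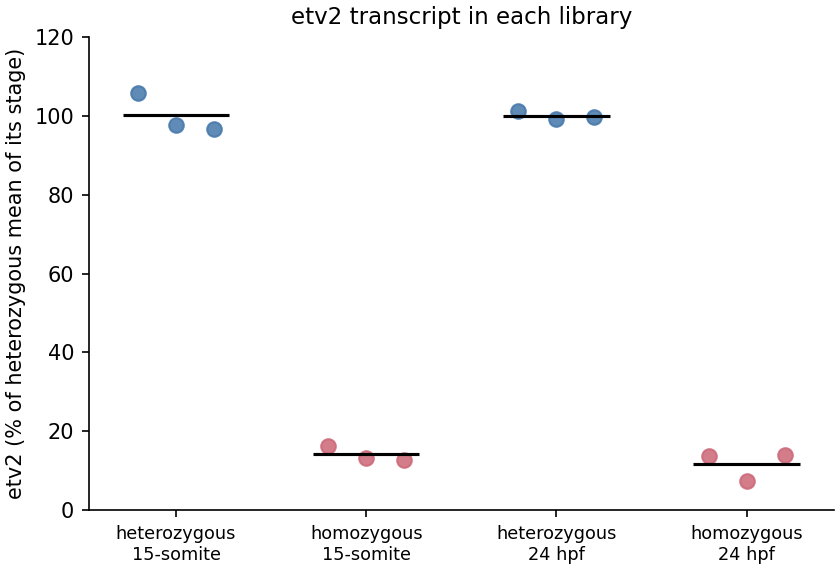
Level of etv2 in each of the 12 libraries, as a percentage of the heterozygous mean of its stage (points: libraries; lines: means of the 3 libraries of a group). Homozygous libraries lay between 7.40% and 16.3%, below every heterozygous library.

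Homozygous embryos were compared with heterozygous embryos at the 15-somite stage to find which genes differ while vessels and blood first form. Genes of endothelial cells, which line blood vessels, were lower as a group. Of 37 endothelial genes tested, 26 fell and 0 rose over all genes tested, and 30 fell and 1 rose when adjusted over the list alone. Their median was -1.85, a 3.61-fold lower level, and 36 lay below 0. The largest named fall was that of gpr182 (ENSDARG00000036616), a receptor gene of endothelium, by 6.37 on the log2 scale (SE 0.57, 82.5-fold, adjusted p = 0.00739). The receptor kinase gene tie1 (ENSDARG00000004105) fell by 4.45 (SE 0.24, 21.8-fold, adjusted p = 0.00128). RASIP1 (ENSDARG00000074829), a gene of vessel lumen formation, fell by 4.22 (SE 0.20, adjusted p = 0.000953), and clec14a, an endothelial surface lectin gene, fell by 4.73. The adaptor gene she fell by 2.38. Among members named after their values were seen, cdh5, the gene of vascular endothelial cadherin (-4.76), the VEGF receptor genes kdrl (-1.41) and flt1 (-5.24) and the ETS factor gene fli1a (-1.10) fell, whereas robo4 stood at 0.29, passed over the list alone and did not pass over all genes (adjusted p = 0.113). The list test by camera gave adjusted p = 8.22e-28, and adjusted p = 0.0163 with an estimated correlation.

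Markers of vein, artery and blood moved less evenly. Of 6 venous genes, 3 fell, all also members of the endothelial list: stab2 (-1.85), flt4 (-2.07) and mrc1a (-5.97). When adjusted over the list alone 4 fell, and without het 2 or het 3 mrc1a had adjusted p = 0.0565 and 0.0515. The size for mrc1a is uncertain, as its homozygous values may lie near the floor. The venous median was -1.25 (camera, adjusted p = 0.00374; adjusted p = 0.186 with an estimated correlation). Of 7 arterial genes only the aquaporin gene aqp8a.1 fell (-2.50, SE 0.22, adjusted p = 0.00540), also when adjusted over the list alone, and the list did not pass (median -0.15, adjusted p = 0.527). Among 8 blood progenitor regulators, tal1 and lmo2, which encode partners of a transcription complex of early blood and endothelium, fell (-1.60, SE 0.08, and -1.21, SE 0.10), and no other member passed over all genes or over the list alone. That list had a median of -0.29 (adjusted p = 0.0284; adjusted p = 0.208 with an estimated correlation), and without het 3 or hom 2 its adjusted p was 0.102 and 0.103. Of 16 myeloid genes, the neutrophil GTPase gene rac2 and the chemokine receptor gene cxcr3.2 fell (-0.96 and -2.46), and 5 fell when adjusted over the list alone. The myeloid median was -0.35 (adjusted p = 0.0144; adjusted p = 0.202 with an estimated correlation). Of 23 erythroid genes, gata1a, the red cell master regulator, rose by 0.41, and cahz, a carbonic anhydrase gene, and nt5c2l1 fell (-0.73 and -0.96). When adjusted over the list alone 4 erythroid genes rose and 3 fell. The erythroid list did not pass (adjusted p = 0.952), with a median of 0.01, a mean of -0.05 and an upward test statistic. Whichever library was left out, nt5c2l1 did not pass (adjusted p 0.0587 to 0.123), nor did gata1a unless it was hom 2 (0.0623 to 0.104), cxcr3.2 unless it was het 2 (0.0518 to 0.0686), or cahz without het 2 (0.0753) or het 3 (0.0604).

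Genes of the embryo's surface tissues were also lower. All 3 hatching gland genes fell: wu:fa26c03 (current symbol ctslb), a cathepsin gene (-1.01, SE 0.10), and the hatching enzyme genes he1b (-1.21, SE 0.13) and he1a (-0.87, SE 0.13). Of 15 epidermis and ionocyte genes 7 fell, 13 when adjusted over the list alone, and all 15 lay below 0, with a median of -0.35. Among them the keratin genes cyt1 (-0.59) and cyt1l (-0.55), icn (-0.69) and EPCAM, an epithelial adhesion gene (-0.36), fell. The camera test gave adjusted p = 0.000249 for hatching gland (adjusted p = 0.208 with an estimated correlation) and adjusted p = 1.75e-08 for epidermis (adjusted p = 0.156 with an estimated correlation). Of 6 endoderm genes, fabp2, a fatty acid binding protein gene of intestine and yolk, fell by 1.74, and 3 fell when adjusted over the list alone (median -0.31, adjusted p = 0.0248; adjusted p = 0.284 with an estimated correlation). The cardiac list was lower (14 genes, median -0.34, adjusted p = 0.0248; adjusted p = 0.284 with an estimated correlation). None of its members passed over all genes by limma, 5 were lower at an unadjusted p below 0.05, and 3 fell when adjusted over the list alone; gata5 stood at -1.0 and hand2 at -0.48. Without het 3 or hom b the cardiac adjusted p was 0.120 and 0.0632. Whichever library was left out, icn and EPCAM did not pass (adjusted p 0.0587 to 0.104 and 0.0623 to 0.117), nor did wu:fa26c03 without het 2 (0.0590), he1b and cyt1 without het 2 (0.0613 and 0.0695) or het 3 (0.0566 and 0.0561), he1a and fabp2 without het 1, het 2, het 3 or hom a (0.0594 to 0.0874 and 0.0641 to 0.0997), or cyt1l without het 2, het 3, hom a or hom b (0.0520 to 0.0695).

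The remaining 12 lists did not pass at the 15-somite stage. Skeletal muscle structure genes had a median of -0.04 (39 genes, adjusted p = 0.952), with eno3 lower by 0.52 and ttnb, a titin gene, higher by 0.44; these 2 passed over all genes and over the list alone. Without het 1 the muscle list was higher, with a median of 0.07 and adjusted p = 0.0483. In the pronephros list (12 genes, median -0.04, adjusted p = 0.931) the sodium pump gene atp1a1a.4 fell by 0.54, the 1 member that passed over all genes and over the list alone. Whichever library was left out, eno3, ttnb and atp1a1a.4 did not pass (adjusted p 0.0549 to 0.111, 0.0698 to 0.154 and 0.0695 to 0.119). No member of the other lists passed over all genes by limma. Myogenic and paraxial mesoderm regulators had a median of 0.07 (30 genes, adjusted p = 0.161), 5 were higher and 2 lower at an unadjusted p below 0.05, and 3 rose when adjusted over the list alone; tbx6 stood at 0.51 and mef2d at 0.39. Neural genes had a median of 0.04 (24 genes, adjusted p = 0.155) and notochord genes 0.14 (6 genes, adjusted p = 0.104), with 4 and 3 genes higher at an unadjusted p below 0.05 and 0 when adjusted over the list alone; elavl3 and pax6b stood at 0.45 and 0.30, and the collagen genes col8a1a and col2a1a at 0.25 and 0.18. Both lists passed without het 1, with adjusted p = 0.0293 and 0.0358. Neural crest and pigment genes had a median of -0.17 (13 genes, adjusted p = 0.155; 2 lower at an unadjusted p below 0.05, 0 when adjusted over the list alone), sclerotome, fibroblast and mural cell genes -0.12 (12 genes, adjusted p = 0.225; 1 and 0) and germ cell genes -0.23 (6 genes, adjusted p = 0.161; 1 and 1). The pigment gene pmela stood at -0.17 and sox10 at 0.11, pdgfrb at -0.52 and col1a2 at -0.12, and the germ cell genes nanos3 at -0.49 and piwil1 at -0.15. Without het 3 nanos3 passed by limma, with adjusted p = 0.0457. Lens genes had a median of -0.19 but a mean of 0.02 and a downward test (4 genes, adjusted p = 0.952; 1 higher at an unadjusted p below 0.05), with cryba4 at -0.34 and cryba2b at -0.04. The hypoxia response list had a median of 2.2e-06, a mean of -0.07 and a downward test (13 genes, adjusted p = 0.952; 1 higher and 1 lower at an unadjusted p below 0.05), with pfkfb3 at 0.19 and ndrg1a at -0.21. The p53 response list had a median of -0.10 (11 genes, adjusted p = 0.328; 0 at an unadjusted p below 0.05) and the cell cycle list -0.05 (18 genes, adjusted p = 0.276; 1 lower), with cdkn1a at -0.26, ccng1 at -0.11, cdk1 at -0.20 and MKI67 at 0.14. None of the genes of these last 4 lists passed when adjusted over the list alone.

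Across all 18907 genes tested at this stage, 618 fell and 122 rose in homozygotes. The counts depended on the fit, with 1209 lower and 727 higher for all 12 libraries in one fit, 195 and 40 with 1 prior spread for all genes, and 643 and 196 with the stricter filter on level. The fall exceeded 2-fold in 265 genes and the rise in 30, and the median changes were -0.85 and 0.52. After those above, the largest named falls were shank3b (-3.74), the claudin gene cldn5b (-3.70), INPP5D (-3.50), KLHL4 (-3.09), arhgef9b (-2.62) and the pyruvate carboxylase gene pc (-2.53). In that same class, the largest named rise was soul5, a heme-binding protein gene, by 3.27 (SE 0.56, adjusted p = 0.0328). Next in that class were lonrf1l at 1.40 (SE 0.09), fam131bb at 1.3, the circadian clock genes cry1a at 1.28 (SE 0.14) and per2 at 1.18 (SE 0.09), fam169b at 1.05, grin2db at 0.94, lonrf1 at 0.92, PPP1R14C (1 of 2) at 0.85 and the clock gene per3 at 0.81. At an unadjusted p below 0.05, 2190 genes were lower and 1775 higher, and 28.7% of genes had separate groups where chance gives 10%. Among calls, 84 of the lower and 25 of the higher genes had no descriptive symbol and are not named. Quantile normalization gave 737 lower and 271 higher genes, and soul5 then stood at 3.97 with adjusted p = 0.0532. The 740 calls dropped to 390, 62 and 90 without het 1, het 2 or het 3, and to 369, 141 and 273 without hom 2, hom a or hom b.

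Some calls among the genes with the largest changes ended when 1 library was left out. Whichever library was left out, grin2db did not pass (adjusted p 0.0581 to 0.124), nor did INPP5D and fam169b unless it was hom 2 (0.0900 to 0.119 and 0.0818 to 0.109), KLHL4 unless it was hom a (0.0778 to 0.147) and lonrf1 unless it was het 3 (0.0521 to 0.0823). The same held for pc without het 2, het 3, hom a or hom b (0.0520 to 0.0978), soul5 without het 2, het 3, hom 2 or hom a (0.0541 to 0.110) and per3 without het 1, het 2, hom a or hom b (0.0549 to 0.0899). It held for cry1a without het 2 (0.0545) or het 3 (0.0532), fam131bb without het 3 (0.0515) or hom a (0.0504), PPP1R14C (1 of 2) without het 2 (0.0749) or hom a (0.0590), and cldn5b without het 2 (0.0534). The falls of gpr182, tie1, RASIP1, shank3b and arhgef9b and the rises of lonrf1l and per2 passed without each library in turn.

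The same comparison was made at 24 hpf, when the main vessels are in place and circulation begins. Endothelial genes were again lower: of 39 tested, 21 fell and 0 rose over all genes tested, 33 fell when adjusted over the list alone, and all 39 lay below 0, with a median of -1.23 (2.35-fold lower). The scavenger receptor gene stab2 (ENSDARG00000045748) fell by 3.11 (SE 0.09, 8.63-fold, adjusted p = 0.000107) and tie2 (ENSDARG00000028663), an angiopoietin receptor gene, fell by 2.36 (SE 0.07, 5.14-fold, adjusted p = 0.000107). The gene vsg1 (current symbol plvapb), of endothelial diaphragms, fell by 2.93 (SE 0.10), and clec14a (-1.66), gpr182 (-3.02), tie1 (-2.91), flt1 (-2.80) and cldn5b (-2.66) fell as well. The camera test gave adjusted p = 3.49e-61, and adjusted p = 0.0131 with an estimated correlation. Of 7 venous genes 4 fell, stab2, mrc1a (-3.21), flt4 (-1.45) and the adaptor gene dab2 (-1.14), and 5 fell when adjusted over the list alone (median -1.45, adjusted p = 1.87e-13; adjusted p = 0.0544 with an estimated correlation). Of 7 arterial genes only aqp8a.1 fell (-6.39, SE 0.48, 83.8-fold), and 2 fell when adjusted over the list alone. The arterial median was -0.12 and the mean -1.03 (adjusted p = 0.000454; adjusted p = 0.0935 with an estimated correlation). Without het 1, het 2, het 3 or hom 2 tie1 and dab2 did not pass (adjusted p 0.0591 to 0.0878 and 0.0516 to 0.0867), nor did flt1 (0.0708) and mrc1a (0.0605) without het 1.

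Myeloid genes were lower at 24 hpf. Of 24 tested, 4 fell over all genes, 15 when adjusted over the list alone, and 21 lay below 0, with a median of -1.30. The 4 were mfap4, a macrophage marker (-4.98, SE 0.60), srgn, a proteoglycan gene of granules (-4.29, SE 0.46), lyz, the lysozyme gene (-2.90, SE 0.23), and lcp1, the leukocyte plastin gene (-1.46, SE 0.17). The size for mfap4 is uncertain, as its homozygous values may lie near the floor. The neutrophil peroxidase gene mpx and the regulators spi1 and irf8, named after their values were seen, stood at -3.65, -1.72 and -2.41 and did not pass over all genes. The camera test gave adjusted p = 3.35e-16, and adjusted p = 0.0131 with an estimated correlation. Among 6 blood progenitor regulators lmo2 fell by 0.63, over all genes and over the list alone; the list had a median and a mean of 0.03 with a downward test (adjusted p = 0.528). Whichever library was left out, lcp1 and lmo2 did not pass (adjusted p 0.0795 to 0.140 and 0.0591 to 0.160), nor did srgn and mfap4 without het 1, het 2, het 3 or hom 3 (0.0859 to 0.150 and 0.121 to 0.150), or lyz without het 1 (0.0567).

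Erythroid genes were higher as a list at 24 hpf. Splits of these libraries that mix the genotypes also called lists by camera, up to 8 where the real split called 9. At the 15-somite stage such splits called up to 5 lists, where the real split called 8. A camera call alone, at either stage, therefore does not show an effect of the genotype. None of the 24 passed over all genes by limma, 18 were higher at an unadjusted p below 0.05, 17 rose when adjusted over the list alone, and 23 lay above 0. The median was 0.34, or 1.27-fold (adjusted p = 2.91e-16; adjusted p = 0.139 with an estimated correlation). The heme synthesis gene urod stood at 0.44 (SE 0.06, adjusted p = 0.0781) and tfr1a, the transferrin receptor gene of red cells, at 0.94 (SE 0.15, adjusted p = 0.134). The 6 globin genes of the list had a median of 0.43 and the 18 other members 0.29. Cardiac genes were higher (14 genes, median 0.26, 13 above 0, adjusted p = 0.000154; adjusted p = 0.216 with an estimated correlation), with the myosin genes vmhc at 0.44 and myl7 at 0.34. Neural crest and pigment genes were higher (15 genes, median 0.13, adjusted p = 0.000454; adjusted p = 0.161 with an estimated correlation), with tyrp1b at 0.24 and dct at 0.17. Pronephros genes were higher by a small margin (12 genes, median 0.25, adjusted p = 0.0499; adjusted p = 0.216 with an estimated correlation), with atp1a1a.4 at 0.37 and hnf1ba at 0.25. Their adjusted p was 0.245 and 0.0687 without het 2 or het 3 and 0.116 and 0.123 without hom 1 or hom 2. It was also above 0.05 with no filter on level (0.0585), a looser (0.0574) or a stricter one (0.0697), with median-centred libraries (0.0505) and by fry (0.128). All 9 lens genes lay below 0 (median -0.15, adjusted p = 0.00517; adjusted p = 0.398 with an estimated correlation), with cryba4 at -0.23 and crybb1 at -0.16, and without het 3 or hom 2 the adjusted p was 0.144 and 0.135. No gene of these 4 lists passed by limma, over all genes or over the list alone, where 4 cardiac, 1 pigment and 3 pronephros genes were higher and 1 lens gene lower at an unadjusted p below 0.05.

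The remaining 12 lists did not pass at 24 hpf, and no member of them passed by limma over all genes or over the list alone. Skeletal muscle structure genes had a median of -0.04 (42 genes, adjusted p = 0.0659; 1 lower at an unadjusted p below 0.05), with tnnc2 at -0.16 and cav3 at -0.13. This list was lower without het 1 or hom 3, with adjusted p = 0.0160 and 0.00590. Myogenic and paraxial mesoderm regulators had a median of -0.04 (29 genes, adjusted p = 0.528; 1 higher, 1 lower) and neural genes -0.04 (24 genes, adjusted p = 0.391; 1 lower), with pax7b at 0.15, tmem8c at -0.15, neurog1 at -0.24 and her4.1 at -0.16. Notochord genes had a median of 0.02, a mean of -0.01 and an upward test (6 genes, adjusted p = 0.897; 0 at an unadjusted p below 0.05), with col8a1a at 0.07 and ntla at 0.03. Hatching gland genes had a median of -0.01 (3 genes, adjusted p = 0.897; 0), with he1a at -0.08 and he1b at 0.03. Epidermis and ionocyte genes had a median of 0.05 (15 genes, adjusted p = 0.469; 1 lower), with icn at -0.33 and grhl3 at -0.12. Endoderm genes had a median of 0.12 (7 genes, adjusted p = 0.0873; 1 higher), with foxa2 at 0.20 and foxa1 at -0.05, and were higher without het 1 or hom 3, with adjusted p = 0.00699 and 0.0272. Sclerotome, fibroblast and mural cell genes had a median of 0.09 (12 genes, adjusted p = 0.227; 1 higher, 1 lower), with pdgfra at 0.36 and col5a1 at 0.10. Germ cell genes had a median of -0.07 (6 genes, adjusted p = 0.528; 1 lower), with nanos3 at 0.26 and tdrd7 at -0.74. The hypoxia response list had a median of 0.05 (13 genes, adjusted p = 0.129; 1 higher), with pdk1 at 0.29 and vegfaa at 0.23. The p53 response and cell cycle lists had medians of -0.07 (11 genes, adjusted p = 0.528; 0) and 0.04 (18 genes, adjusted p = 0.141; 0), with sesn1 at -0.11, baxa at -0.07, cdk1 at 0.09 and mcm5 at 0.06.

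Of 19429 genes tested at 24 hpf, 47 fell and 5 rose, so 90.4% of calls were lower. The fall exceeded 2-fold in 43 genes. All 5 genes that rose are named: lonrf1l by 0.98 (SE 0.10), OTOA, an inner ear matrix gene, by 0.93 (SE 0.11), PARP6 (3 of 4) by 0.82, the cholesterol hydroxylase gene cyp46a1 by 0.78 and the clock gene cry1a by 0.66 (SE 0.06). No rise exceeded 2-fold by limma. At an unadjusted p below 0.05, 779 genes were lower and 601 higher, and 12.8% of genes had separate groups where chance gives 10%. The 52 calls dropped to 11, 27 and 22 without het 1, het 2 or het 3 and to 37, 31 and 31 without hom 1, hom 2 or hom 3. Whichever library was left out, cry1a and OTOA did not pass (adjusted p 0.0584 to 0.0905 and 0.0665 to 0.173), nor did lonrf1l and PARP6 (3 of 4) unless it was hom 3 (0.0866 to 0.115 and 0.0897 to 0.209) and cyp46a1 unless it was het 2 (0.0637 to 0.124).

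The stages were then compared, to find which changes were shared and which differed. Among the 18139 genes tested at both, 30 fell at both stages, where independent lists of 591 and 40 genes share 1.3 (one-sided Fisher's exact test, p = 7.42e-37, adjusted p = 1.48e-36). They included gpr182, tie1, tie2, stab2, flt4, kdrl, clec14a, RASIP1, lmo2 and etv2 itself. At both stages 3 genes rose, cry1a, lonrf1l and OTOA, where 0.0254 is the number for independent lists (p = 9.88e-07 by the same exact test, over both directions adjusted p = 9.88e-07). These exact tests treat genes as independent. Many of the shared genes are endothelial and fell together, so the p-values do not measure the spread between libraries. No gene was called in opposite directions. Across genes, which are not independent replicates, the changes at the 2 stages had a Pearson correlation of 0.18 and a Spearman correlation of -0.01. The overlap of 33 genes dropped to 21 without het 2 or het 3 of the 15-somite stage, and to 10, 19 and 18 without het 1, het 2 or het 3 of 24 hpf.

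The genotype effect differed between the stages for 604 genes (limma interaction), with a difference, 24 hpf minus 15-somite, above 0 for 448 and below 0 for 156. Of the 604, 351 had fallen at the 15-somite stage and differed upward, 42 had risen there and differed downward, and 204 were called at neither stage. Of the 591 genes that fell at the 15-somite stage, 354 differed, and 343 of these were not called at 24 hpf. For tal1 the difference was 1.54 (SE 0.12), from a fall of 1.60 to a value of -0.07 that did not pass at 24 hpf. The falls of clec14a and RASIP1 were smaller at 24 hpf by 3.08 (SE 0.28) and 2.62 (SE 0.24), whereas those of aqp8a.1, stab2 and vsg1 were larger, with differences of -3.89 (SE 0.56), -1.26 (SE 0.14) and -1.39 (SE 0.30). The size for aqp8a.1 is uncertain, as its homozygous values at 24 hpf may lie near the floor. The leukocyte gene lcp1 went from -0.38, which did not pass, to a fall of 1.46. Of the 22 lists, 9 differed by camera, and none with an estimated correlation, where the lowest adjusted p was 0.130; the other 13 had adjusted p between 0.0637 and 0.761. Dividing the 24 hpf libraries into groups that mix the genotypes, with the 15-somite genotypes kept, gave up to 642 genes. The count dropped to 313, 338, 351 and 286 without het 2, het 3, hom a or hom b of the 15-somite stage, and to 288, 179, 291, 238 and 206 without het 1, het 2, het 3, hom 1 or hom 2 of 24 hpf.

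**Figure D2:**
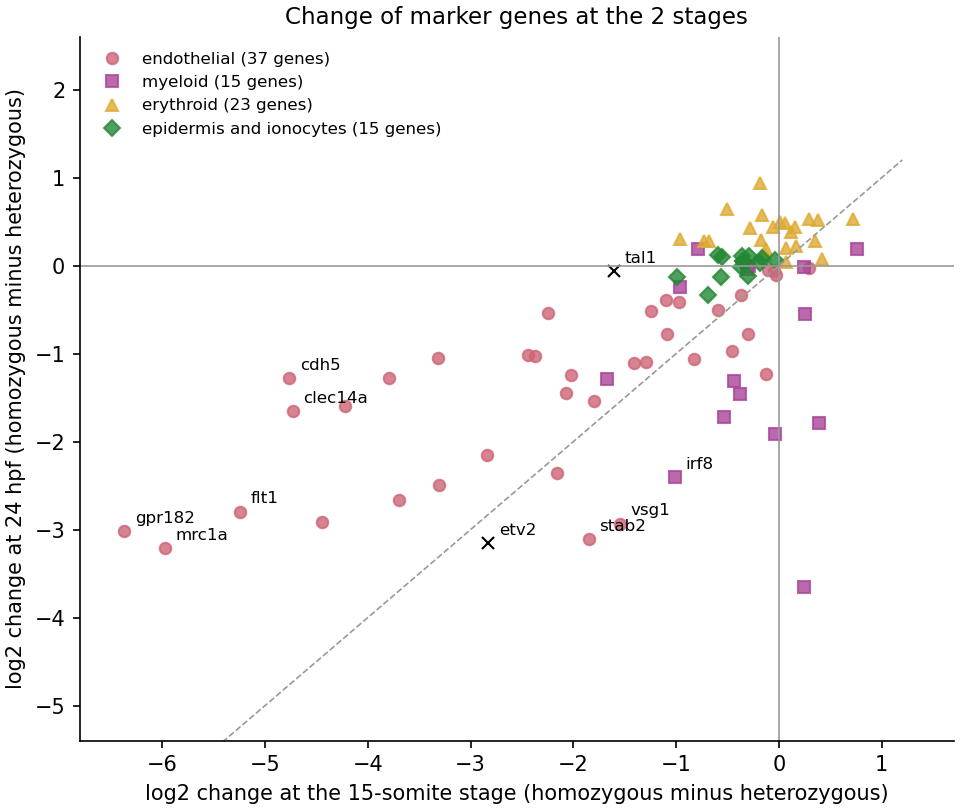
Change of genes in the endothelial (37 genes), myeloid (15), erythroid (23) and epidermis and ionocyte (15) lists at the 15-somite stage (x axis) and at 24 hpf (y axis), homozygous minus heterozygous, log2; crosses mark etv2 and tal1 and the dashed line marks equal change. Most endothelial genes lay below 0 on both axes, erythroid genes lay on both sides of 0 on the x axis, among them nt5c2l1 at -0.96 and gata1a at 0.41, and the 23 shown lay above 0 on the y axis, and tal1 stood at -1.60 and -0.07.

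Calls were more frequent on chromosome 16, which holds etv2 in assembly GRCz12tu, than elsewhere. Of the 15-somite calls with a known chromosome, etv2 left out, 58 of 659 (8.80%) lay on it, against 4.35% of uncalled genes (odds ratio 2.12, two-sided Fisher's exact test, p = 1.25e-06, adjusted over the stages p = 2.5e-06). The share was 13.4% of the genes that rose and 8.01% of those that fell (adjusted exact p = 0.0013 for each). Without genes within 5 Mb of etv2 it was 7.96% against 3.56%. At 24 hpf 4 of 46 calls (8.70%) lay on chromosome 16, against 4.46% of uncalled genes, which did not pass (exact p = 0.149).

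Further groups of genes were chosen because their members changed at the 15-somite stage, so no test of these groups is given. Of genes of the circadian clock and of the response to light, 12 were chosen among those that rose, with a median of 0.80 and values from 0.43 to 1.55, among them cry5 at 1.55, tatdn2 at 1.37 and per1b at 0.79. At 24 hpf 11 of the 12 lay above 0, with a median of 0.27, and only cry1a and lonrf1l passed. Of genes of the yolk syncytial layer, the tissue that exports yolk lipid to the embryo, and liver-type genes, 13 were chosen among those that fell, with a median of -1.68, among them apoa2 at -2.09, fabp1b.1 at -2.08, the transferrin gene tfa at -1.99 and the regulator hnf4a at -1.19. At 24 hpf the same 13 genes had a median of 0.12.

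**Figure D3:**
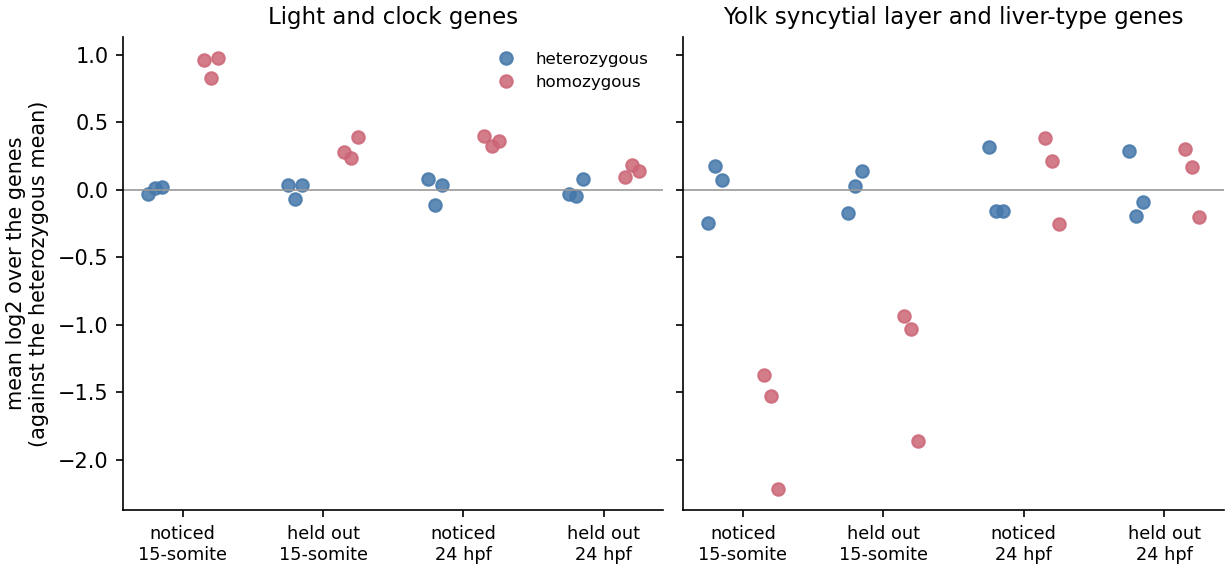
Mean log2 value of light and clock genes (left) and yolk syncytial layer and liver-type genes (right) in each library, relative to the heterozygous mean of its stage; genes noticed in the data are shown beside genes held out until tested. At the 15-somite stage the homozygous libraries lay at 0.83 to 0.97 for the noticed light and clock genes and at -2.21 to -1.37 for the noticed yolk genes.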

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

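The tests on other splits of the libraries in this part were chosen only after the result was seen; the test of the difference between the stages was chosen beforehand.

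The endothelial and blood genes below stood out because their genotype effect differed between the stages in the limma interaction test (differences are 24 hpf minus 15-somite, log2). Of the named genes, 28 differed, 22 of them with a smaller change at 24 hpf. More of the called named genes were chosen for their change at the 15-somite stage, so smaller changes at 24 hpf are partly due to that choice. The fall was smaller at 24 hpf for the endothelial genes gpr182 (3.35), clec14a (3.08), RASIP1 (2.62), tie1 (1.54) and she (1.35), for shank3b (2.57) and arhgef9b (1.44), for the blood and endothelial regulators tal1 (1.54) and lmo2 (0.57), and for the neutrophil gene rac2 (0.72). The fall was larger at 24 hpf for aqp8a.1 (-3.89, of uncertain size near the floor), vsg1 (-1.39), stab2 (-1.26) and lcp1 (-1.08). Among erythroid genes cahz (1.003), nt5c2l1 (1.26), tfr1a (1.12) and urod (0.49) differed upward; the first 2 fell at the 15-somite stage and none of the 4 passed at 24 hpf.

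In other tissues, falls at the 15-somite stage were smaller or absent at 24 hpf for the keratin genes cyt1 (0.71) and cyt1l (0.65), EPCAM (0.47), the cathepsin gene wu:fa26c03 (0.997), fabp2 (1.85), the sodium pump gene atp1a1a.4 (0.91) and eno3 (0.51). Rises at the 15-somite stage were smaller at 24 hpf for the clock gene per2 (-0.66) and for fam131bb (-1.14), and the neuronal gene elavl3, which passed at neither stage, differed by -0.51. Of 22 lists, 9 differed by camera, given as median differences: endothelial (0.62, adjusted p = 0.000137), arterial (-0.26, adjusted p = 0.0350), blood progenitor regulators (0.53, adjusted p = 0.00208), erythroid (0.32, adjusted p = 4.88e-05), cardiac (0.61, adjusted p = 0.00216), hatching gland (0.997, adjusted p = 0.00427), epidermis and ionocytes (0.39, adjusted p = 6.71e-09), endoderm (0.46, adjusted p = 0.00637) and neural crest and pigment (0.32, adjusted p = 0.00758). With an estimated correlation none of them differed (lowest adjusted p = 0.130).

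When all 12 libraries were divided in other ways, 2 of 100 drawn splits, of 200 possible, gave as many differing genes as the 604 of the real one, the real one included. The other was larger, with 642 genes, and kept the 15-somite genotypes while placing het 1, hom 1 and hom 2 of 24 hpf in one group. The 8 drawn splits that kept the 15-somite genotypes gave at least 186 genes, and the rest at most 1. The count therefore follows the 15-somite effect, these splits do not test the difference between the stages, and the size of the count does not show that the 24 hpf effect was small. For the overlap, 1 of 200 pairs of splits, the real one, shared as many calls (33, against 0 as the highest of the others). No other split called a gene at either stage, so no other pair had calls to share, and this count says nothing about the overlap beyond the counts at each stage.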

How the results depend on the processing

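The stricter and the looser filter on level (row medians in the top level class, or of at least 4) were chosen after seeing the data, and so were the tests on other splits; the other alternatives were planned.

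Of 67 called results for named genes and 17 for lists, 0 changed direction under any alternative run here. For the genes this was largely fixed in advance. Called genes had separate groups, so leaving out a library could not reverse them, and filters and prior spreads leave the difference itself unchanged. Counted over all alternatives, called genes stayed past the threshold in 474 values and fell short in 136 at the 15-somite stage, and in 252 and 86 at 24 hpf; called lists did so in 112 and 16, and in 131 and 22. Named genes that were not called in the main fit passed in 15 values at the 15-somite stage. Of these, 6 came with all 12 libraries in one fit, 5 with quantile normalization, 3 with the stricter filter and 1 without 1 library. At 24 hpf they passed in 2 values, both with all 12 libraries in one fit.

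The number of higher genes at the 15-somite stage (122) was 196 with the stricter filter, 271 with quantile normalization, 40 with 1 prior spread for all genes, 30 at 2-fold or more, 727 with all 12 libraries in one fit, and 11 to 59 without 1 library. The number of lower genes (618) was 195 with 1 prior spread, 265 at 2-fold or more, 1209 with all 12 libraries in one fit, and 51 to 331 without 1 library. Lists lower at the 15-somite stage numbered 1 with an estimated correlation, and lists higher numbered 1 by fry and 0 to 3 without 1 library. At 24 hpf the higher genes (5) numbered 1 with a replicate block, 3 with quantile normalization, 2 with 1 prior spread, 0 at 2-fold or more by limma, and 0 to 4 without 1 library; the lower genes (47) numbered 22 with the block and 10 to 37 without 1 library. Lists lower at 24 hpf numbered 2 with an estimated correlation, and lists higher 0 with it and 1 by fry. The difference between the stages (604 genes) was 240 with 1 prior spread and 179 to 685 without 1 library, and the overlap (33 genes) was 19 with the stricter filter and 10 to 31 without 1 library. A 2-fold limit removes genes by construction. Fewer libraries leave less power, which does not account for counts that rose, such as the 685 without het 1 of the 15-somite stage. For such rises and for the other alternatives the cause was not tested. Of the 740 calls at the 15-somite stage 209 were shared with 1 prior spread and 732 with quantile normalization, and of the 52 at 24 hpf 32 and 49. With 1 prior spread 17 of the called results for named genes at the 15-somite stage fell short, and 9 at 24 hpf.

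Apart from the estimated correlation and libraries left out, called lists lost their call at the 15-somite stage for cardiac (adjusted p = 0.114 with the stricter filter, 0.108 with all 12 libraries in one fit, 0.0786 by fry), venous (0.114 with the stricter filter) and myeloid (0.0611 with all 12 libraries). At 24 hpf this held for lens (0.353 with all 12 libraries, 0.358 by fry), and by fry for cardiac (0.196) and neural crest (0.0760); pronephros is described in the report. Lists gained a call for notochord at the 15-somite stage (0.0446 by fry), and at 24 hpf for skeletal muscle (0.0312 with the stricter filter, 0.0487 with quantile normalization) and hypoxia response (0.010003 with the stricter filter).

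Results that were not called could reverse in the direction of their test, here as medians. At the 15-somite stage these were arterial (0.143), skeletal muscle (-0.0311), pronephros (-0.0330), hypoxia response (0.0409) and erythroid (0.0130) with the stricter filter, erythroid (0.0130) with all 12 libraries in one fit, and skeletal muscle (-0.0153), lens (-0.132) and the gene cryba2b (0.0118) with quantile normalization. Without 1 library the values were -0.207 to 0.0803 for cryba2b, -0.0960 to 0.0657 for skeletal muscle, -0.311 to -0.0590 for lens, -0.101 to 0.0758 for erythroid and -0.0914 to 0.0358 for hypoxia response. At 24 hpf they were -0.0202 to 0.0750 for ntla, -0.22 to 0.11 for he1a, -0.21 to 0.26 for he1b, -0.10 to 0.00208 for foxa1, 0.00526 to 0.0608 for notochord, -0.19 to 0.18 for hatching gland, -0.0499 to -0.0124 for myogenic regulators, -0.0830 to 0.0875 for p53 response and -0.0478 to 0.0153 for neural. The cause was not tested.

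With 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached. In each case 1 split, the real one, gave a count as large. At the 15-somite stage the real and the highest other counts were 122 and 0 higher genes, 618 and 0 lower genes and 8 and 5 lists; at 24 hpf they were 5 and 0, 47 and 0, and 9 and 8. Camera thus also called lists in splits that mix the genotypes, at 24 hpf nearly as many as in the real one.

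The replicate numbers at 24 hpf showed no clear pairing of the libraries. Residuals of the same number correlated at 0.094, 0.013 and -0.007, and those of different numbers at -0.094 to 0.083. So few values do not exclude a pairing, and the labels do not state whether equal numbers belong together. With the block 13 of the called results for named genes at 24 hpf passed, etv2 at adjusted p = 0.0439, and 10 did not: lonrf1l (0.162), PARP6 (0.0789), cyp46a1 (0.0643), cry1a (0.121), srgn (0.139), gpr182 (0.0640), dab2 (0.0994), lmo2 (0.162), mfap4 (0.0789) and lcp1 (0.0789). No replicate block was fitted at the 15-somite stage or between the stages, because 2 homozygous columns there share a name and which library each holds is not given. Not run were other pseudocounts, edgeR and DESeq2, since the values hold no counts, and a mean of at least 50, replaced by the stricter filter.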

Other observations

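In this part the tests of library scaling, of embryo age and of chromosome 16 were chosen only after the result was seen, and the gene groups were chosen after some of their values were seen; the tests on held-out genes were written before those genes were looked at.

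Genes outside the lists that fell at both stages are named here after their values were seen, and no shared function was tested for them. They included scarf1, a scavenger receptor gene of endothelium (-4.46 at the 15-somite stage and -1.56 at 24 hpf), CD93, an endothelial lectin gene (-4.16 and -2.53), the phosphatase gene dusp5 (-3.11 and -1.63), the growth factor gene tgfb1b (-2.11 and -1.41), the aquaporin gene aqp1a.1 (-1.40 and -0.98), the collagen gene col8a2 (-1.62 and -1.69), f13a1b (-1.20 and -1.03), itga10 (-1.42 and -1.07), micall2a (-1.88 and -1.90) and ccdc88b (-1.56 and -1.38). OTOA rose at both (1.76 and 0.93).

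Clock and light-response genes such as per2 and cry1a were higher in homozygotes at the 15-somite stage. Of 12 chosen, 11 still passed with quantile normalization. So did 732 of all 740 calls at this stage, and the 12 were chosen among calls, so this does not test library scaling for them. Held-out light-induced genes had medians of 0.22 at the 15-somite stage (10 genes, 9 above 0, among them tefa at 0.33 and neil1 at 0.41, which did not pass at adjusted p = 0.0572 and 0.0506; list adjusted p = 0.00215 by camera over the 10 tests of added groups, and 0.108 with an estimated correlation) and 0.14 at 24 hpf (12 genes, 8 above 0; adjusted p = 0.0136, and 0.111 with an estimated correlation). The 10 tests include groups chosen for their change, which makes this adjustment more lenient. Light exposure or time of day that differed between the genotypes before freezing, for example while embryos were sorted by GFP, may explain part of the rise. Held-out genes would also rise if the genotype itself raised genes of the light response, so they do not tell these explanations apart. An effect of the genotype on these genes stays open, as neither handling times nor light were recorded in the labels.

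Genes of the yolk syncytial layer, many of which liver also expresses, and of hatching gland and epidermis were lower in homozygotes at the 15-somite stage. Held-out yolk syncytial layer genes, 10 in all, had a median of -1.35 (all below 0, 6 called, among them apoa1a at -1.42; adjusted p = 2.2e-08, and 0.168 with an estimated correlation), and a median of 0.10 at 24 hpf (adjusted p = 0.476). Muscle structure genes had a median of -0.0366 (SD 0.19) where the hatching gland genes had -1.01, so muscle did not share the fall. How far the muscle list moves with a small difference in age was not measured, so younger homozygous embryos were not ruled out. With quantile normalization 8 lists were lower as well, among them lists of endothelial and blood genes. Camera compares a list with other genes, so this count says little about library scaling. With an estimated correlation 1 of the 8, the endothelial list, stayed called by camera in the main fit (hatching gland adjusted p = 0.208 and epidermis 0.156). Less tissue of the yolk surface in the homozygous 15-somite libraries, whether lost in handling or less of it formed, may underlie this pattern. Those 2 sources were not separated, and the genotype itself stays open.

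Genes called at the 15-somite stage were more frequent on chromosome 16. Within 5 Mb of etv2 6 of 128 genes were called (4.69%), against 52 of 574 farther along (9.06%, Fisher's exact test, p = 0.113). Variants carried along with the insertion cannot be told apart from a genotype effect, because siblings homozygous for the insertion also share the linked stretch, whose length is unknown. Without the noticed and held-out yolk genes the share among lower calls was 7.37% (adjusted exact p = 0.00436), so those genes alone did not account for the excess. Other neighbouring genes that change together stayed in this test, which treats genes as independent, so gene clusters were not excluded. No biological explanation was tested.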
